A study of Mus musculus with 48 samples.

How the data were processed

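Cerebellar RNA from 48 mice, 1 animal per array, was measured on Affymetrix MG-U74Av2 arrays. Per the labels, 5 transgenic lines were compared with nontransgenic controls, which the authors' series design calls littermates. Each line carried exon 1 of huntingtin (Htt) with a run of glutamines. In lines A39 and A61 a nuclear exclusion signal (NES) was joined to exon 1 with 142 glutamines. In lines S46 and S25 a nuclear localization signal (NLS) was joined to the same stretch of 142 glutamines, and in line X50 the NLS was joined to 18 glutamines. The arrays fell into 14 groups, given by line, age and genotype, with 3 or 4 arrays in each. Groups were taken from titles and descriptions. For 3 of the 4 controls of line A61 the title named line A39, whereas the description and the replicate number named A61, and these were kept as A61 controls. The transgenic arrays of S46 at the younger age were titled 3 months and described as 3.5 months; 3.5 months was used, as for their controls.

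The deposited table gave 1 intensity per probe set and array on a linear scale. The authors had named MAS5 as their software, without a version. Every value was above 0 and the 2% trimmed mean was between 500.2 and 500.3 in each array, so the authors had already scaled the arrays to one level. Of 12488 probe sets, 66 were Affymetrix controls. The deposited record files of the arrays (unit: other, text fields of the fluidics station and scanner) were used only to find scan days, chip lots and stations, which gave 6 scan days and 2 chip lots. Detection calls and raw probe values were not used here, so signal over background could not be assessed per array. For arrays, the number of animals limits the precision.

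Gene symbols came from the platform's gene table matched to RefSeq gene identifiers. It listed 11251 probe sets, of which 10855 had 1 symbol and 396 had several, and 1237 had no listing; 10839 symbols were matched through a gene identifier. Probe sets without 1 symbol were tested and counted but not named.

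Values were computed with R 4.3.3 and limma 3.58.1. Each array was scaled to a common 2% trimmed mean, a pseudocount of 18.7 (the 10th percentile of all values) was added, and log2 was taken. Probe sets whose mean signal over all 48 arrays lay at or above the 40th percentile were tested, which left 7453, of which 6715 had 1 symbol. A single limma model (lmFit, eBayes) with a mean for each group was fitted to all arrays, with 34 residual and 3.73 prior degrees of freedom. The 7 comparisons were transgenic minus control at each line and age. A further 7 tests asked whether 2 such effects differed. P values were two-sided and adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. All adjusted p values given for genes or gene lists are from limma. Folds and percentages are from the fitted log2 values, pseudocount included. SE is the standard error of the log2 difference.

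Named genes followed a rule. In each comparison they were the 12 largest rises and the 12 largest falls among probe sets past the threshold with 1 symbol, with every transgenic array on one side of every control array, and not sex-linked. Where none passed, the 6 with the smallest p were given as values that did not pass. Htt, up to 4 changed members of each list, up to 10 genes called in the most comparisons, and up to 6 rises and 6 falls in each difference test were added. Members of fixed lists and genes of the sex check are named beside them.

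The 24 gene lists were markers of Purkinje cells, granule cells, Bergmann glia and astrocytes, oligodendrocytes and myelin, microglia and macrophages, interneurons and GABA synthesis, choroid plexus, vessels, meninges and fibroblasts, blood cells, and neighbouring brainstem and midbrain, and genes for heat shock proteins and chaperones, endoplasmic reticulum stress, proteasome subunits, cholesterol synthesis, immediate early responses, interferon and MHC class I, calcium signalling, glutamate and GABA receptors, genes known to fall in Huntington's disease striatum, mitochondrial respiratory chain subunits, ribosomal proteins, p53 targets, and histones and chromatin regulators. Lists, comparisons, tests, the rule for named genes and most alternatives were fixed before the data were examined. Each list was tested with camera over 5639 genes, 1 probe set per gene, with the correlation between genes preset at 0.01, again with an estimated correlation, and with fry. Adjusted p values of lists are over the 24 lists within a comparison. Few genes were in 2 lists: the Purkinje and calcium lists shared Cacna1a and Cacna1g, the calcium and striatum lists shared Camk4, Hpca and Ryr1, and the receptor and granule lists shared Gabra6, Gabrd and Grin2c. The choroid plexus and meninges lists shared Igf2, the striatum and immediate early lists Egr1, and the immediate early and p53 lists Btg2.

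Mean scores per array were compared between genotypes with exact two-sided permutation tests, whose smallest p is 0.0286 for 4 against 4 arrays and 0.1 for 3 against 3. Their adjusted p values are over all marker scores, the 3' over 5' ratios and array agreement within a comparison. Effects were correlated over the 7453 probe sets for 21 pairs of comparisons; genes are not independent replicates, so no p is given. No 2 comparisons shared arrays.

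The procedure was tested on simulated data with the same group sizes. Noise was drawn independently for each gene and array, with the same spread in all arrays for a probe set. With this noise the procedure recovered between 71.6% and 89.6% of changes of 1 on the log2 scale and between 25.4% and 44.8% of changes of 0.5. The share of false calls was 2.80% to 7.69%. Of 50 random lists without a change, 4 had a camera p below 0.05. As the simulated genes were independent, this cannot check the preset correlation for genes that vary together. Arrays were checked for duplicates over 1128 pairs (highest r 0.976, none identical), for sex, for 3' over 5' ratios of Gapdh and actin, and for agreement with the other arrays of the comparison.

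Alternatives were quantile normalization, no scaling, the pseudocount divided and multiplied by 4, no filter and a filter at the 60th percentile, a fit to only the arrays compared, a replicate block, sex, scan day, animal identifier prefix as a random block, array weights, and leaving out each array. Added after seeing the data were sex read from the Xist and Eif2s3y signals, the fluidics station as a block, leaving out the 4 arrays of lowest agreement, and exchanging 2 controls whose record files carried each other's scan day. No samples were left out of the main values. Male arrays of S25, the station block in S25, and A61 without the controls titled A39 each leave 1 control, which is assumed to vary like the other groups.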

Results

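The 48 arrays measured RNA of the cerebellum in mouse lines made to ask how a polyglutamine stretch inside and outside the nucleus contributes to neurological signs. Profiles were made at the age when each line with 142 glutamines first failed on the rotarod, and in A39 and S46 also later. The NES line A39 gave 4 transgenic and 4 control arrays at 4 months and 3 of each at 10 to 10.5 months. The NES line A61 gave 4 of each at 8 months. The NLS line S46 gave 4 of each at 3.5 months and 3 of each at 10 months. The NLS line S25 gave 3 transgenic arrays at 3 months and 3 controls at 2.5 to 3 months. The NLS line X50, with 18 glutamines, gave 3 of each at 16 months. Gapdh 3' over 5' ratios ran from 0.80 to 1.16 and actin ratios from 1.08 to 1.80. The mean correlation of an array with the others of its comparison ran from 0.897 to 0.963. The mouse Htt probe set did not pass the test in any comparison, with log2 differences from -0.19 to 0.20.

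Does polyglutamine joined to a nuclear exclusion signal change the cerebellar transcriptome when signs begin? Where the protein lay in the cells was not measured here. In A39 at 4 months (n = 4 and 4), genes of Purkinje cells fell. Rgs8, a regulator of G protein signalling abundant in these cells, fell to 48.8% of the control signal (log2 -1.04, SE 0.10, adjusted p = 6.17e-09). Homer3, a scaffold of their glutamate receptors, fell to 50.8% (-0.98, SE 0.12) and Calb1, their calcium buffer calbindin, to 61.1% (-0.71, SE 0.09). Marcks, an actin-binding substrate of protein kinase C, rose 2.69-fold (log2 1.43, SE 0.19, adjusted p = 8.12e-06). Basp1, a membrane protein of growing axons, rose 2.65-fold (1.40, SE 0.23). B2m, the light chain of MHC class I, rose 2.37-fold (1.24, SE 0.25), and Jun 2.39-fold (1.26, SE 0.21). The steepest fall relative to its error was that of Fam107b, to 41.3% (-1.28, SE 0.10, adjusted p = 4.64e-12).

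Of the 12 Purkinje markers measured in A39 at 4 months, 7 fell, 0 rose and 5 did not pass, and 11 fell when adjusted over the list alone. The list median was -0.56 (camera adjusted p = 8.17e-18, and 4.96e-05 with an estimated correlation). Granule cell markers showed no shift (15 measured, 1 rose, 2 rose and 1 fell when adjusted over the list alone, median -0.0029, adjusted p = 0.725), although Calb2, calretinin, rose 1.57-fold (log2 0.65, SE 0.14). Of 11 oligodendrocyte and myelin genes 3 fell, among them Car2, a carbonic anhydrase (-0.53, SE 0.11), and 5 fell when adjusted over the list alone. Their median was -0.30 (adjusted p = 3.4e-06, and 0.0355 with an estimated correlation). Calcium signalling genes fell as a list (22 measured, 4 fell, 5 when adjusted over the list alone, median -0.16, adjusted p = 0.000357, and 0.0335 with an estimated correlation). Without control array 1 or transgenic array 3 the median was -0.10 or -0.09. Its examples were Inpp5a, an inositol phosphate phosphatase (-0.82, SE 0.12), and Atp2a2 and Atp2a3, calcium pumps of the endoplasmic reticulum (-0.80, SE 0.14, and -0.72, SE 0.14). Ribosomal protein genes rose slightly as a list (24 measured, 1 rose, 15 when adjusted over the list alone, median 0.30, adjusted p = 3.42e-09, and 0.0335 with an estimated correlation). Cholesterol synthesis genes fell (13 measured, 3 fell, 1 rose and 4 fell when adjusted over the list alone, median -0.12, adjusted p = 0.0231, and 0.0467 with an estimated correlation), but the adjusted p was 0.0517 without control array 2 and the median -0.07 without transgenic array 1.

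Among 16 immediate early genes of A39 at 4 months, Jun rose and 3 fell (the same counts adjusted over the list alone), with Nr4a1, a nuclear receptor induced by activity, at 37.2% of control (log2 -1.43, SE 0.30). That list passed with the preset correlation (median -0.31, adjusted p = 0.00057) and not with an estimated one (adjusted p = 0.119). The same held for proteasome subunits (32 measured, 0 rose, 1 adjusted over the list alone, median 0.13, adjusted p = 0.000357, and 0.221 with an estimated correlation). It held also for respiratory chain subunits (51 measured, 0 rose on either adjustment, median 0.16, adjusted p = 0.000357, and 0.221 with an estimated correlation; median 0.07 without control array 4). Microglia markers passed likewise (10 measured, 0 rose, 1 adjusted over the list alone, median 0.23, adjusted p = 0.0339, and 0.221 with an estimated correlation). They did not without control array 1, 2 or 3 or transgenic array 3 (adjusted p = 0.0717, 0.0648, 0.0836 and 0.12). Interneuron genes were lower (8 measured, 1 fell, 2 adjusted over the list alone, median -0.29, adjusted p = 0.0219, and 0.0927 with an estimated correlation), except without control array 1 or transgenic array 4 (0.0506 and 0.0697). So were endoplasmic reticulum stress genes (16 measured, 0 fell, 2 adjusted over the list alone, median -0.19, adjusted p = 0.0138, and 0.142 with an estimated correlation), except without control array 4 or transgenic array 4 (0.113, with a median of -0.11, and 0.0697). Over all genes, 118 of 7453 probe sets changed, 34 up and 84 down. Without transgenic array 3 the count was 67. Of 45 named calls, 22 passed with every array left out in turn and 11 also in every other alternative of normalization, filter, model or arrays. A fit to these 8 arrays alone gave 23 probe sets.

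At 10 months, A39 showed lower Purkinje genes together with higher Gfap and microglia genes (n = 3 and 3). Homer3 stood at 41.8% of control (log2 -1.26, SE 0.14, adjusted p = 5.53e-08) and Calb1 at 51.0% (-0.97, SE 0.11). Also lower was Slc1a6, the glutamate transporter of Purkinje cells, at 48.5% (-1.04, SE 0.17). Gfap, the filament protein of astrocytes, rose 1.92-fold (0.94, SE 0.17, adjusted p = 0.000462) and C1qa, a complement subunit made by microglia, 1.89-fold (0.92, SE 0.19). Marcks rose 3.01-fold (1.59, SE 0.22) and Basp1 2.45-fold (1.29, SE 0.27). Nab2, a corepressor of early growth response factors, fell to 31.7% (-1.66, SE 0.20), and Col18a1, a collagen of basement membranes, to 19.6% (-2.35, SE 0.35).

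Of the 12 Purkinje markers in A39 at 10 months, 9 fell and 3 did not pass, and 11 fell when adjusted over the list alone (median -0.79, adjusted p = 2.8e-25, and 1.81e-06 with an estimated correlation). Of 10 microglia markers 3 rose and 7 did when adjusted over the list alone (median 0.59, adjusted p = 4.62e-08, and 0.00247 with an estimated correlation). The Bergmann glia and astrocyte list, which holds Gfap, did not pass (14 measured, 1 rose, median -0.03, adjusted p = 0.828). Of 22 calcium signalling genes 5 fell, with Atp2a3 at -1.11 (SE 0.16), Atp2a2 at -1.03 (SE 0.16) and Hpcal1, a calcium sensor, at -0.75 (SE 0.15). Adjusted over the list alone 9 fell and 1 rose (median -0.32, adjusted p = 7.87e-07, and 0.00231 with an estimated correlation). Cbln1, a synapse organizer released by granule cells, fell (-0.64, SE 0.12), the only one of 15 granule markers to pass over all genes. Adjusted over the list alone 6 fell, and the list passed only with the preset correlation (median -0.27, adjusted p = 0.0155, and 0.104 with an estimated correlation), not without transgenic array 3 or control array 3 (0.167, with a median of -0.17, and 0.0867). Choroid plexus markers, from tissue next to the cerebellum, were higher (8 measured, 0 rose, 1 adjusted over the list alone, median 0.64, adjusted p = 0.0174, and 0.329 with an estimated correlation; 0.0533 without control array 2). Blood cell markers were lower (6 measured, 0 fell, 1 adjusted over the list alone, median -0.69, adjusted p = 0.0128, and 0.0724 with an estimated correlation). Without control array 1 their median was -0.31 (adjusted p = 0.133).

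Of the other lists in A39 at 10 months, ribosomal protein genes passed with the preset correlation (24 measured, 1 rose, 2 adjusted over the list alone, median 0.23, adjusted p = 4.65e-06, and 0.0748 with an estimated correlation). Oligodendrocyte genes (11 measured, 1 fell, 3 adjusted over the list alone, median -0.06, adjusted p = 0.0256, and 0.316 with an estimated correlation) did not pass without control array 1 or transgenic array 1 (0.0749 and 0.39). With transgenic array 1 left out the median was 0.04. Proteasome subunits (32 measured, 0 rose on either adjustment, median 0.14, adjusted p = 0.00549, and 0.317 with an estimated correlation) did not pass without control array 2 (0.0585). Nor did cholesterol synthesis genes (13 measured, 1 fell on either adjustment, median -0.12, adjusted p = 0.0207, and 0.0507 with an estimated correlation; 0.0585 without that array, and a median of -0.06 without transgenic array 1), among which Idi1, an isomerase of the pathway, fell (-0.74, SE 0.15). Genes known to fall in Huntington's disease striatum (15 measured, 1 rose and 2 fell, 1 and 3 adjusted over the list alone, median -0.13, adjusted p = 0.0203, and 0.0507 with an estimated correlation) depended on the same array (0.0614 without it, with a median of -0.07). Glutamate and GABA receptor genes (16 measured, 1 fell, 4 adjusted over the list alone, median -0.17, adjusted p = 0.0155, and 0.108 with an estimated correlation) did not pass without control array 1 or 3 (0.0501, with a median of -0.06, and 0.0723), and had a median of -0.10 without transgenic array 2. Over all genes, 141 probe sets changed, 46 up and 95 down. The count was 91 without control array 1, 80 without control array 2, 88 without transgenic array 1 and 82 without transgenic array 2. Of 45 named calls 24 passed with every array left out in turn, 19 in every other alternative and 17 in both. A fit to these 6 arrays alone gave 42 probe sets.

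The second NES line, A61, had fewer changed genes at 8 months (n = 4 and 4). Marcks rose 2.26-fold (log2 1.17, SE 0.19, adjusted p = 0.000794) and Gfap 1.77-fold (0.83, SE 0.14, adjusted p = 0.00153). Rgs8 fell to 59.7% of control (-0.74, SE 0.10), Fam107b to 62.0% (-0.69, SE 0.10) and Abcc8, a subunit of potassium channels gated by ATP, to 62.0% (-0.69, SE 0.13). Calb1 was at 74.4% (-0.43, SE 0.09, adjusted p = 0.0291) and Homer3 at 67.6% (-0.57, SE 0.12, adjusted p = 0.0198). Those 2 calls depended on single arrays. For Homer3 the adjusted p was 0.159 without transgenic array 2, 0.0993 without control array 1 and 0.0518 without control array 2. For Calb1 it stayed below 0.05 only without transgenic array 3, with a highest value of 0.133. A fit to these 8 arrays alone called Gfap but not Marcks, Rgs8, Fam107b or Abcc8 (Rgs8 adjusted p = 0.116). Without the 3 controls titled A39, which leaves 1 control, Rgs8 was at -0.78 (SE 0.17) and Marcks at 0.99 (SE 0.29).

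Among the 12 Purkinje markers in A61, 2 fell and 10 did not pass, and 7 fell when adjusted over the list alone (median -0.32, adjusted p = 5.09e-09, and 0.0069 with an estimated correlation). The score of these markers, against the mean of the controls, was -0.11 in transgenic array 3 and -0.45 to -0.40 in the other three. This was the only list call of A61 that held with an estimated correlation. Oligodendrocyte genes passed with the preset correlation (11 measured, 0 fell, 1 adjusted over the list alone, median -0.24, adjusted p = 0.000239, and 0.0885 with an estimated correlation). So did interneuron genes (8 measured, 0 fell, 3 adjusted over the list alone, median -0.36, adjusted p = 0.00709, and 0.0574 with an estimated correlation). Calcium signalling genes were lower (22 measured, 1 fell, 4 adjusted over the list alone, median -0.09, adjusted p = 0.00519, and 0.0769 with an estimated correlation), and proteasome subunits higher (32 measured, 0 rose on either adjustment, median 0.12, adjusted p = 0.00519, and 0.381 with an estimated correlation). Microglia markers (10 measured, 0 rose, 3 rose and 1 fell adjusted over the list alone, median 0.23, adjusted p = 0.0165, and 0.202 with an estimated correlation) did not pass without transgenic array 4 (0.0882, with a median of 0.14). Genes known to fall in Huntington's disease striatum (15 measured, 1 fell on either adjustment, median -0.12, adjusted p = 0.0125, and 0.0547 with an estimated correlation) did not without control array 3 (0.0573, with a median of -0.07), and had a median of -0.07 without control array 4. Interferon and MHC class I genes (10 measured, 0 fell on either adjustment, median -0.29, adjusted p = 0.014, and 0.195 with an estimated correlation) did not pass without control array 1, control array 2 or transgenic array 3 (0.156, 0.081 and 0.0841, with medians of -0.23, -0.19 and -0.19). Over all genes 19 probe sets changed, 4 up and 15 down. The count was 8 and 10 without control arrays 1 and 3, and 11, 7, 31 and 9 without transgenic arrays 1, 2, 3 and 4. It was 5 in a fit to these 8 arrays alone, and 6 with the 1 control not titled A39, of which 2 were among the 19. Of 13 named calls 5 passed with every array left out in turn, and 0 in every other alternative.

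With the same glutamine stretch joined to the NLS, line S46 showed no gene past the threshold at 3.5 months (n = 4 and 4). Calb1 was at 113% of control (log2 0.17, SE 0.09, adjusted p = 0.484), Rgs8 at 105% and Homer3 at 92.4%. Marcks was at 131% (0.39, SE 0.19, adjusted p = 0.451). The smallest p values belonged to Impdh1, an enzyme of guanine nucleotide synthesis (-0.48), Pttg1ip (0.51), Gtf3c5, a subunit of an RNA polymerase III factor (0.92), and Phkg2, a phosphorylase kinase subunit (0.60), each with adjusted p = 0.0751. They were followed by Ptpn5, a neuronal phosphatase (-0.68, adjusted p = 0.08), and Fgd1 (0.90, adjusted p = 0.127). Among 12 Purkinje markers 0 passed over all genes and 1 was higher when adjusted over the list alone (median 0.06, adjusted p = 0.526). Lists that passed with the preset correlation were ribosomal protein genes (24 measured, median 0.15, adjusted p = 0.0243), proteasome subunits (32 measured, median 0.09, adjusted p = 0.0243) and respiratory chain subunits (51 measured, median 0.10, adjusted p = 0.0258). These had 0 members past the threshold on either adjustment and adjusted p = 0.723 for each with an estimated correlation. Without transgenic array 4 their adjusted p was 0.378 for each, and without control array 4 it was 0.289, 0.465 and 0.464. Their medians were then 0.11, 0.04 and 0.07 without transgenic array 4, and 0.09, 0.05 and 0.07 without control array 4. Ribosomal genes did not pass without control array 3 (0.0754), nor respiratory chain subunits without transgenic array 3 (0.312). The limma count of 0 stood beside 835 probe sets with an unadjusted p below 0.05, where 373 were expected by chance. It became 5 without control array 1, 2 without transgenic array 1, and 1 without control array 2, control array 3, transgenic array 2 or transgenic array 3.

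At 10 months Purkinje genes were lower in S46 as well (n = 3 and 3), and 45 probe sets fell both here and in A39 at 10 months (0.727 expected). Cck, a neuropeptide, fell to 27.6% of control (log2 -1.86, SE 0.26, adjusted p = 8.88e-06) and Hk2, a hexokinase, to 29.7% (-1.75, SE 0.31). Calb1 fell to 49.2% (-1.02, SE 0.11) and Homer3 to 43.8% (-1.19, SE 0.14). Lower too were Slc1a6, at 44.7% (-1.16, SE 0.17), and Kitl, the ligand of the Kit receptor, at 46.4% (-1.11, SE 0.15). Basp1 rose 3.00-fold (1.59, SE 0.27), Marcks 2.86-fold (1.51, SE 0.22) and Alcam, an adhesion molecule, 1.76-fold (0.81, SE 0.16).

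Of the 12 Purkinje markers in S46 at 10 months, 6 fell and 6 did not pass, and 10 fell when adjusted over the list alone (median -0.78, adjusted p = 3.51e-28, and 5.8e-07 with an estimated correlation). Probe sets of one gene differed: Pcp2, a protein named after Purkinje cells, fell by 1.29 (SE 0.17) at one probe set and was at -0.37 (adjusted p = 0.795) at the one used for the list. Of 22 calcium signalling genes 5 fell, with Atp2a3 at -1.23 (SE 0.16), Inpp5a at -0.98 (SE 0.14) and Atp2a2 at -0.93 (SE 0.16). Adjusted over the list alone 8 fell and 1 rose (median -0.20, adjusted p = 1.47e-10, and 7.94e-05 with an estimated correlation). Genes known to fall in Huntington's disease striatum fell as a list (15 measured, 1 fell, 4 adjusted over the list alone, median -0.25, adjusted p = 7.33e-05, and 0.000609 with an estimated correlation). Npy, a neuropeptide of interneurons, fell (-1.05, SE 0.20). The interneuron list passed with the preset correlation (8 measured, 1 fell, 2 adjusted over the list alone, median -0.13, adjusted p = 0.0128, and 0.0803 with an estimated correlation). Without control array 1 its median was -0.04 (adjusted p = 0.0679), and without transgenic array 2 also -0.04 (adjusted p = 0.0489).

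In S46 at 10 months choroid plexus markers were higher with the preset correlation, with a median of 0.74 (8 measured, 0 rose, 2 adjusted over the list alone, adjusted p = 0.000117, and 0.183 with an estimated correlation). Meninges and fibroblast markers had a median of 0.15 (11 measured, 1 rose on either adjustment, adjusted p = 0.00395, and 0.124 with an estimated correlation). Brainstem and midbrain markers did not pass (6 measured, median -0.15, adjusted p = 0.749). Ribosomal protein genes passed with the preset correlation (24 measured, 0 rose on either adjustment, median 0.24, adjusted p = 4.38e-06, and 0.097 with an estimated correlation). So did microglia markers (10 measured, 0 rose on either adjustment, median 0.22, adjusted p = 0.0423, and 0.311 with an estimated correlation), which did not without control array 1 or 3 or transgenic array 1 or 2 (0.46, with a median of 0.14, and 0.0801, 0.154 and 0.0996). Over all genes 74 probe sets changed, 17 up and 57 down. The count was 44 without transgenic array 1, 43 without transgenic array 2 and 49 without control array 3. The 3 transgenic arrays, labelled female, had the Xist and Eif2s3y signals of males. With sex read from these signals in the model 51 probe sets were called, 46 of them among the 74. The controls had the female pattern and another animal identifier prefix than the transgenic arrays. Within this comparison, sex pattern and prefix thus cannot be told apart from genotype. Of 36 named calls 21 passed with every array left out in turn, and 19 in every other alternative too. A fit to only the arrays of this comparison gave 54 probe sets, 34 of them among the 74.

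The NLS line S25 showed the steepest falls of the series, at 3 months (n = 3 and 3). Cck fell to 8.99% of control (log2 -3.48, SE 0.26, adjusted p = 5.31e-13). Car8, a protein that binds the inositol trisphosphate receptor in Purkinje cells, fell to 19.2% (-2.38, SE 0.24) and Slc1a6 to 21.0% (-2.25, SE 0.17). Ppp1r17, a phosphatase inhibitor of Purkinje cells, fell to 23.4% (-2.10, SE 0.17), Rgs8 to 25.1% (-1.99, SE 0.12) and Calb1 to 28.3% (-1.82, SE 0.11). Complement genes of microglia rose, C1qb 3.36-fold (1.75, SE 0.27) and C1qa 3.12-fold (1.64, SE 0.19), as did Ctss, a lysosomal protease, 2.43-fold (1.28, SE 0.19), and Gfap 2.27-fold (1.18, SE 0.17). Basp1 rose 3.87-fold (1.95, SE 0.27) and B2m 2.66-fold (1.41, SE 0.29).

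Of the 12 Purkinje markers in S25, 9 fell and 3 did not pass, and 11 fell when adjusted over the list alone (median -1.66, adjusted p = 4.6e-35, and 5.08e-08 with an estimated correlation). Of 10 microglia markers 6 rose and 8 did when adjusted over the list alone (median 1.02, adjusted p = 1.69e-11, and 0.000226 with an estimated correlation). Of 22 calcium signalling genes 6 fell, among them Inpp5a at -1.86 (SE 0.14), Atp2a3 at -2.00 (SE 0.16) and Atp2a2 at -1.37 (SE 0.16). Adjusted over the list alone 13 fell (median -0.41, adjusted p = 7.87e-11, and 7.37e-05 with an estimated correlation). Of 16 endoplasmic reticulum stress genes 3 fell, with Hspa5, the chaperone BiP, at 47.6% (-1.07, SE 0.21). Adjusted over the list alone 5 fell (median -0.34, adjusted p = 1.71e-05, and 0.0104 with an estimated correlation). Cholesterol synthesis genes fell as a list (13 measured, 1 fell, Idi1 at -0.74, SE 0.15, 3 adjusted over the list alone, median -0.33, adjusted p = 0.0117, and 0.0209 with an estimated correlation), except without transgenic array 1 (0.0534, with a median of -0.17). Of 16 immediate early genes 4 fell, with Nr4a1 at 28.4% (-1.81, SE 0.34) and Bdnf, a neurotrophin, at 60.8% (-0.72, SE 0.16). Adjusted over the list alone 6 fell and 1 rose (median -0.20, adjusted p = 0.00215, and 0.154 with an estimated correlation). Against the 1 male control alone, Hspa5 was at -0.87 (SE 0.29), Idi1 at -0.43 (SE 0.20), Nr4a1 at -1.64 (SE 0.49) and Bdnf at -0.72 (SE 0.23), none of them past the threshold.

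Bergmann glia and astrocyte markers were higher in S25 (14 measured, 1 rose, 6 adjusted over the list alone, median 0.20, adjusted p = 0.0117, and 0.154 with an estimated correlation; 0.056 without control array 3). Ribosomal protein genes were higher too (24 measured, 0 rose on either adjustment, median 0.18, adjusted p = 0.00231, and 0.226 with an estimated correlation). Choroid plexus markers had a median of 0.91 (8 measured, 1 rose, 3 adjusted over the list alone, adjusted p = 0.0194, and 0.339 with an estimated correlation), and did not pass without transgenic array 1 or 2 or control array 3 (0.0778, with a median of 0.54, 0.0517 and 0.0639). Granule markers (15 measured, 2 fell on either adjustment, median -0.13, adjusted p = 0.0441, and 0.205 with an estimated correlation) lost their call without transgenic array 1 or 2 or control array 2 or 3 (0.0778, 0.129, 0.115 and 0.056), with medians from -0.14 to -0.24. So did glutamate and GABA receptor genes (16 measured, 2 fell, 3 adjusted over the list alone, median -0.19, adjusted p = 0.0441, and 0.205 with an estimated correlation; 0.0534, 0.144, 0.0826 and 0.0921). Over all genes 272 probe sets changed, 109 up and 163 down. All transgenic arrays were from males and from 1 fluidics station, whereas 2 of 3 controls were from females. These 2 were also the ones from the other station, aged 2.5 months and with another animal identifier prefix, so sex, station, age and prefix cannot be told apart. The male arrays, and equally the station as a block, set the 3 transgenic arrays against the same 1 control, with 131 and 122 probe sets (98 and 95 of them among the 272). In that contrast Cck was at -3.28 (SE 0.37), Calb1 at -1.84 (SE 0.16), C1qa at 1.61 (SE 0.27) and B2m at 1.49 (SE 0.41, adjusted p = 0.0532). Of 53 named calls 37 passed with every array left out in turn, and 22 in every other alternative too.

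Line X50, with 18 glutamines and the nuclear signal, served as the control for glutamine length at 16 months (n = 3 and 3). Calb1 was at 106% of control (log2 0.09, SE 0.11, adjusted p = 0.962), Rgs8 at 118% and Marcks at 130%. No Purkinje marker passed on either adjustment (median 0.12, adjusted p = 0.0885). The limma test called 2 probe sets, both lower. They were Atp5md, a small subunit of ATP synthase, at 52.8% (-0.92, SE 0.16, adjusted p = 0.014), and Ndufb9, a subunit of respiratory complex I, at 61.6% (-0.70, SE 0.14, adjusted p = 0.0427). For Atp5md the adjusted p was 0.374 without control array 3, 0.224 without transgenic array 1 and 0.093 without transgenic array 3. For Ndufb9 it reached 0.768 without control array 3 and stayed below 0.05 only without control array 2. The count was 0 without control array 3, transgenic array 1 or transgenic array 3, and 1 without transgenic array 2.

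Respiratory chain subunits were slightly lower as a list in X50 (51 measured, 1 fell on either adjustment, median -0.17, adjusted p = 2e-08). So were proteasome subunits (32 measured, 0 fell on either adjustment, median -0.17, adjusted p = 0.000427), ribosomal protein genes (24 measured, 0 fell on either adjustment, median -0.12, adjusted p = 0.00415) and heat shock genes (25 measured, 0 fell, 1 adjusted over the list alone, median -0.13, adjusted p = 0.0169). Histone and chromatin genes were higher (21 measured, 0 rose on either adjustment, median 0.14, adjusted p = 0.0432). With an estimated correlation none held, with adjusted p = 0.346 for respiratory chain subunits, 0.363 for histones and 0.461 for the other three. Ribosomal genes did not pass without control array 3 (0.133, with a median of -0.07), and heat shock genes not without transgenic array 1 or control array 1 (0.0797, and 0.332 with a median of -0.08). Histone genes did not without control array 3, transgenic array 1 or transgenic array 3 (0.187, with a median of 0.06, 0.133 and 0.0624). The transgenic arrays had all gone through one wash run and the controls through another, so wash run and genotype cannot be told apart here. The Gapdh 3' over 5' ratio was also higher in every transgenic array of X50 (0.883 to 0.941) than in every control (0.80 to 0.840; difference 0.0911, exact p = 0.1, the smallest possible, adjusted p = 0.467). Neither of the 2 named calls of X50 passed with every array left out in turn, or in every other alternative.

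Which genes changed in more than 1 line? In 5 of the 7 comparisons 9 probe sets were lower and 2 higher, and none was called in opposite directions. The named ones were Calb1, Fam107b, Homer3, Rgs8, Washc2 (part of an endosomal actin complex), Ywhah (an adaptor protein that binds phosphoserine) and Zdhhc14 (a palmitoyltransferase), all lower, and Marcks, higher. Rgs8 ran from -0.74 (SE 0.10) in A61 to -1.99 (SE 0.12) in S25, and was at 0.07 in S46 at 3.5 months and 0.24 in X50, neither past the threshold. The rise of Marcks in S25 (1.24, SE 0.22) was 1.05 (SE 0.32, adjusted p = 0.0975) against its 1 male control. In A61 the calls of Calb1, Homer3, Washc2, Ywhah and Zdhhc14 ended with single arrays left out, with a highest adjusted p of 0.222 (Ywhah). The call of Zdhhc14 also ended without transgenic array 3 in A39 at 4 months (0.052), without control array 3 in S46 at 10 months (0.0774), and without transgenic or control array 3 in A39 at 10 months (0.0743 and 0.0609).

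**Figure D1:**
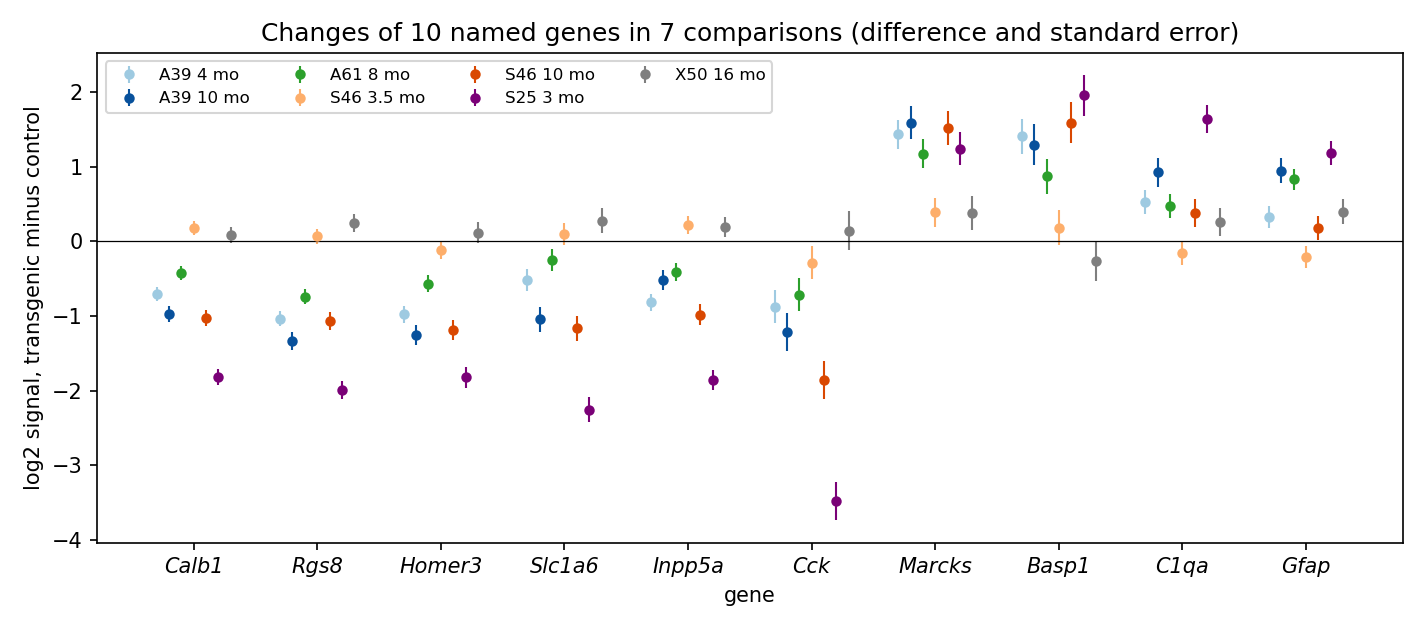
Log2 difference between transgenic and control arrays, with standard error, for recurrently called genes across the 7 comparisons. Rgs8 lies at -1.99 in S25 and at 0.24 in X50, and Marcks at 1.59 in A39 at 10 months.

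Calls overlapped more than expected by chance between the ages of A39, and between each pair of A39, A61, S46 at 10 months and S25. S46 at 3.5 months had 0 calls, so none could be shared between the ages of S46, and the 2 calls of X50 were shared with no other comparison. Between A39 at 4 and at 10 months 55 probe sets fell in both (1.07 expected) and 9 rose in both (0.21 expected). Between A39 at 10 months and S25, an NES and an NLS line, 69 fell in both (2.08 expected) and 20 rose in both. Between S46 at 10 months and S25, 50 fell (1.25 expected) and 11 rose in both. No probe set was called in opposite directions in any pair. Across all 7453 probe sets the effects correlated with Pearson r = 0.411 (Spearman rho 0.376) between the ages of A39 and 0.448 (0.390) between A39 at 10 months and S25, although genes are not independent replicates. Pearson r was 0.13 between the ages of S46 and -0.0575 to 0.0140 between X50 and the others. The 163 probe sets that fell in S25 had medians of -0.45, -0.55 and -0.28 in A39 at 4 months, A39 at 10 months and A61, of -0.41 in S46 at 10 months, of 0.06 in S46 at 3.5 months and of 0.05 in X50.

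The mean of the 12 Purkinje markers and that of the 15 granule markers were compared per array (exact permutation tests, two-sided). With 3 against 3 arrays no difference could pass after adjustment. With 4 against 4 a difference could pass only if many of the measures adjusted together reached the smallest p. None passed, which thus is no sign of an absent difference. The Purkinje score of transgenic arrays was lower by a log2 difference of -0.57 in A39 at 4 months (exact p = 0.0286, adjusted p = 0.133), -0.34 in A61 (exact p = 0.0571, adjusted p = 0.133), and -0.80, -0.76 and -1.39 in A39 at 10 months, S46 at 10 months and S25 (exact p = 0.1 each, the smallest that 3 against 3 arrays allow, adjusted p = 0.28, 0.56 and 0.233). It was 0.04 in S46 at 3.5 months (exact p = 0.486, adjusted p = 0.892) and 0.12 in X50 (exact p = 0.2, adjusted p = 0.525). Granule scores differed by -0.02, -0.03, -0.16, -0.07, -0.16, 0.02 and 0.03 in the same order (adjusted p = 1, 0.4, 0.525, 0.56, 0.233, 0.892 and 0.817). In S25 they too separated the genotypes fully (exact p = 0.1). The Purkinje minus granule score differed by -0.55, -0.31, -0.65, -0.69, -1.23, 0.02 and 0.09 (exact p = 0.0286, 0.0286, 0.1, 0.1, 0.1, 0.886 and 0.2, not adjusted).

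**Figure D2:**
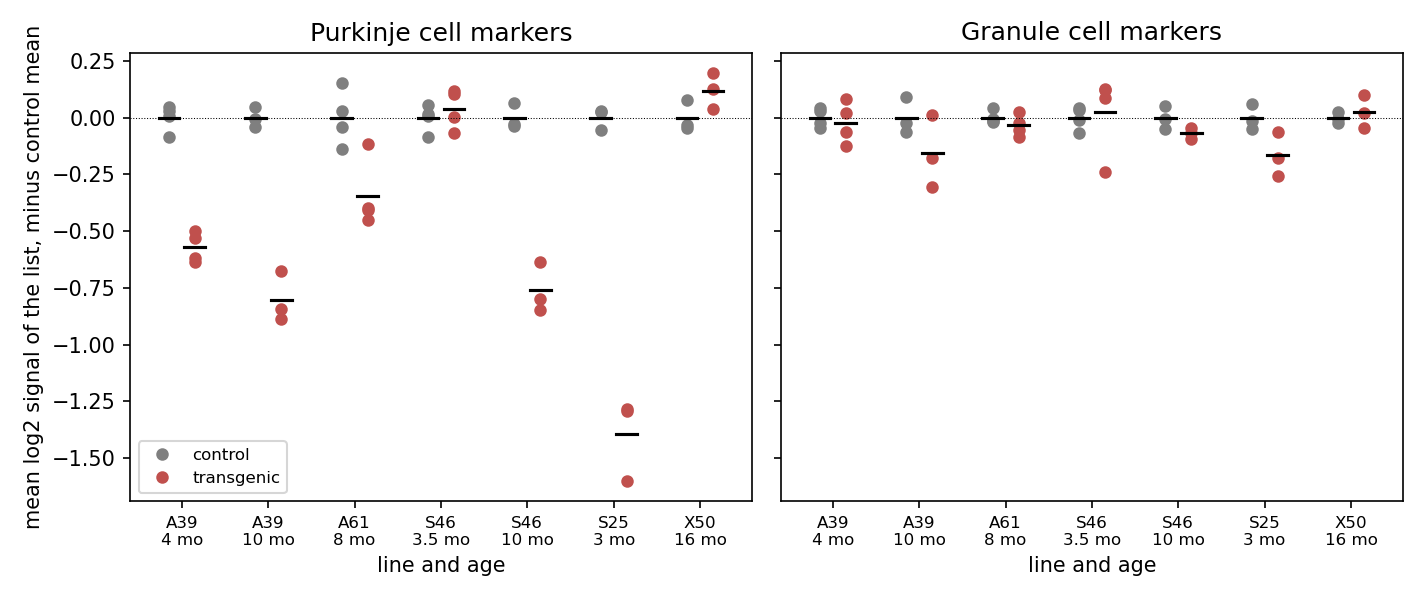
Mean log2 signal of the Purkinje and granule cell markers in each array, relative to the mean of the controls of its comparison; each point is 1 array. Purkinje scores lie lower in transgenic arrays of the 5 comparisons with changed genes of 142 glutamine lines, by -0.34 to -1.39 on average, while granule scores differ by -0.16 to 0.03 over all 7.

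Did age, line, construct or glutamine length change the effect itself? In S46 the effect at 10 months differed from that at 3.5 months in 30 probe sets, 29 of them lower. At 10 months the sex pattern and animal identifier prefix went with genotype, and at 3.5 months they did not. Age thus cannot be told apart from these here. Ppp1r17 differed by -1.32 (SE 0.22, adjusted p = 0.00057), Pcp2 by -1.29 (SE 0.22), Slc1a6 by -1.26 (SE 0.22) and Rmdn3, a protein of contacts between mitochondria and endoplasmic reticulum, by -1.21 (SE 0.18). At the other Pcp2 probe set, the one used for the list, the effect was -0.37 at 10 months and 0.11 at 3.5 months. As lists, Purkinje markers (-0.75, adjusted p = 2.63e-21, and 9.74e-06 with an estimated correlation) and calcium signalling genes (-0.36, adjusted p = 1.13e-07, and 0.0009 with an estimated correlation) differed. Choroid plexus markers did with the preset correlation (1.41, adjusted p = 3.52e-06, and 0.133 with an estimated correlation), as did meninges and fibroblast markers (0.26, adjusted p = 0.024, and 0.28 with an estimated correlation). So did genes known to fall in Huntington's disease striatum (-0.19, adjusted p = 0.024, and 0.0539 with an estimated correlation). In A39, limma called 0 probe sets between 10 and 4 months (259 with an unadjusted p below 0.05, where 373 were expected by chance), and 1 without transgenic array 3 of 10 months. Purkinje markers differed there by -0.27 (adjusted p = 0.00176, and 0.25 with an estimated correlation) and granule markers by -0.20 (adjusted p = 0.0251, and 0.25 with an estimated correlation). Microglia markers differed by 0.41 (adjusted p = 0.000399, and 0.143 with an estimated correlation) and respiratory chain subunits by -0.09 (adjusted p = 0.00528, and 0.437 with an estimated correlation).

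The NLS lines S46 and S25 and the NES lines A39 and A61 at their first ages differed in 2 probe sets, neither with a single gene symbol. That count was 7 and 0 without transgenic arrays 3 and 2 of S25, and 6 and 0 without its controls 2 and 3. It was 4 without transgenic array 3 and 5 without control array 2 of S46, 0 and 1 without transgenic arrays 1 and 2 of A39, and 0 without transgenic array 3 of A61. Oligodendrocyte genes, whose list did not pass in S46 or S25 at these ages, were lower in the NES than in the NLS lines (difference 0.28, adjusted p = 3.11e-06, and 0.102 with an estimated correlation). Purkinje markers differed by -0.18 (adjusted p = 0.00128, and 0.204 with an estimated correlation). Microglia markers differed by 0.22 (adjusted p = 0.00481, and 0.204 with an estimated correlation) and interferon genes by 0.23 (adjusted p = 0.0124, and 0.252 with an estimated correlation). The p values of NLS against NES measure spread within lines, not among lines of a construct, of which there were 2 each. First ages also differed, 3.5 and 3 months in the NLS and 4 and 8 months in the NES lines. Construct thus cannot be told apart from line or age here. S46 and S25 themselves differed at 3.5 and 3 months in 151 probe sets, 44 higher and 107 lower in S25. Cck differed by -3.19 (SE 0.34, adjusted p = 1.53e-08), Slc1a6 by -2.36 (SE 0.22), C1qa by 1.80 (SE 0.25) and Fkbp5, a chaperone of steroid receptors, by 2.14 (SE 0.40). Lists that differed with an estimated correlation too were Purkinje markers (-1.54, adjusted p = 2.95e-07), microglia markers (0.96, adjusted p = 0.000938), calcium signalling (-0.41, adjusted p = 0.000307), endoplasmic reticulum stress (-0.41, adjusted p = 0.00727) and cholesterol synthesis (-0.34, adjusted p = 0.0201). With the preset correlation alone, choroid plexus markers (1.27, adjusted p = 0.00147, and 0.257 with an estimated correlation), Bergmann glia markers (0.33, adjusted p = 0.00601, and 0.143 with an estimated correlation) and granule markers (-0.30, adjusted p = 0.027, and 0.173 with an estimated correlation) differed. The same held for immediate early genes (-0.22, adjusted p = 0.00174, and 0.164 with an estimated correlation) and heat shock genes (-0.15, adjusted p = 0.0173, and 0.42 with an estimated correlation). With the station as a block, which leaves 1 control in S25, the count was 90 and Fkbp5 was at 1.66 (adjusted p = 0.101).

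Against X50, the effect in S46 at 10 months differed in 38 probe sets, 3 higher and 35 lower. Cck differed by -2.00 (SE 0.37, adjusted p = 0.00155), Pcp2 by -1.47 (SE 0.24), Atp2a3 by -1.45 (SE 0.23), Slc1a6 by -1.43 (SE 0.24) and Atp5md by 1.15 (SE 0.23). At the other Pcp2 probe set, the one used for the list, the effect was -0.37 in S46 at 10 months and -0.03 in X50. The Purkinje list differed by -0.94 (adjusted p = 1.3e-21, and 8.51e-06 with an estimated correlation) and calcium signalling genes by -0.44 (adjusted p = 1.09e-08, and 0.000368 with an estimated correlation). The count was 24 without transgenic array 2 of S46. The lines also differed in age, 10 against 16 months. Wash run and genotype could not be told apart in X50, whose values enter every difference here. Nor could sex pattern, identifier prefix and genotype be told apart in S46 at 10 months. Atp5md was at 0.23 in S46 and at -0.92 in X50, where its call ended with single arrays left out. With the preset correlation alone, ribosomal protein genes differed by 0.35 (adjusted p = 3.1e-08, and 0.0566 with an estimated correlation), respiratory chain subunits by 0.20 (adjusted p = 6.73e-06, and 0.234 with an estimated correlation) and proteasome subunits by 0.26 (adjusted p = 3.75e-05, and 0.285 with an estimated correlation). Immediate early genes differed by -0.38 (adjusted p = 0.0133, and 0.328 with an estimated correlation) and genes known to fall in striatum by -0.18 (adjusted p = 0.0398, and 0.0833 with an estimated correlation).

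At 10 months, S46 and A39 differed in 2 probe sets. They were Btbd3, a regulator of dendrite orientation, at -0.06 in S46 and -0.93 in A39 (difference 0.87, SE 0.16), and Strn, a calmodulin-binding scaffold, at -0.59 and 0.76 (difference -1.35, SE 0.25), both with adjusted p = 0.0178. The count was 0 without control array 1, control array 2 or transgenic array 3 of A39 or transgenic array 2 of S46, and 1 without transgenic array 1 or 2 of A39 or without transgenic array 1, transgenic array 3, control array 1 or control array 2 of S46. With sex read from the Xist and Eif2s3y signals in the model the count was also 0. Sex pattern and identifier prefix went with genotype in S46 at this age. Microglia markers were lower in S46 than in A39 by -0.36 (adjusted p = 0.000346, and 0.0451 with an estimated correlation). Blood markers were higher by 0.91 (adjusted p = 0.000641, and 0.0226 with an estimated correlation) and cholesterol genes by 0.22 (adjusted p = 0.0117, and 0.0226 with an estimated correlation); the blood difference draws on the A39 value, whose median was -0.31 without control array 1 there. Oligodendrocyte genes (0.06, adjusted p = 0.0121, and 0.394 with an estimated correlation) and meninges markers (0.21, adjusted p = 0.0263, and 0.394 with an estimated correlation) differed with the preset correlation alone. Line and age cannot be told apart between the NES lines, A61 at 8 months and A39 at 4 months. An unadjusted p below 0.05 was reached by 288 probe sets there, where 373 were expected by chance, and limma called 0. The count was 4 without transgenic array 2 of A61 and 1 without its transgenic array 3 or control array 4. Purkinje markers were less reduced in A61 by 0.26 (adjusted p = 0.000178, and 0.0992 with an estimated correlation). Respiratory chain and ribosomal genes differed by -0.15 and -0.21 (adjusted p = 2.25e-07 and 1.99e-06, and 0.103 and 0.0992 with an estimated correlation). Choroid plexus markers, from another tissue, were lower in A61 by -0.72 (adjusted p = 0.0151, and 0.558 with an estimated correlation) and interferon genes by -0.29 (adjusted p = 0.00115, and 0.0992 with an estimated correlation). Endoplasmic reticulum stress genes differed by 0.22 (adjusted p = 0.000178, and 0.0992 with an estimated correlation) and immediate early genes by 0.18 (adjusted p = 0.00347, and 0.241 with an estimated correlation).

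**Figure D3:**
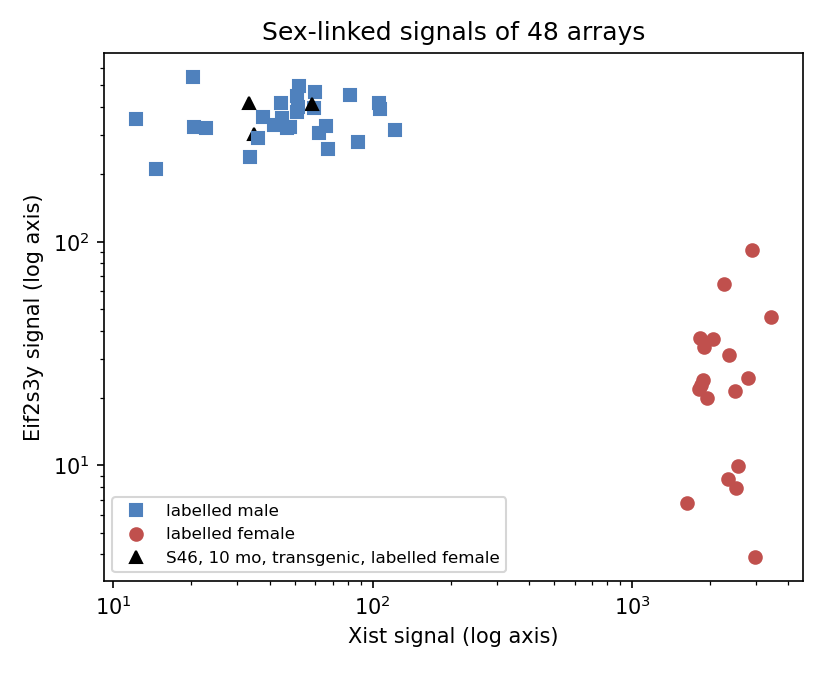
Xist against Eif2s3y signal (log scales) in the 48 arrays, coloured by the sex in the labels. The 3 transgenic arrays of S46 at 10 months are labelled female and lie with the males, whose Xist signals are 12.2 to 121, against 1624 to 3420 in the female pattern.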

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

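The tests of exchanged arrays, dilution, RNA quality, cell loss and a missing transgene were chosen after the result was seen; those of sex and of noisy arrays were written before. Lower Purkinje markers in the 142 glutamine lines were weighed first. Dilution of the cerebellum by neighbouring tissue was excluded as the whole cause, since granule markers changed by at most 19.5% of the Purkinje change. RNA quality was excluded as the whole cause, since at least 97.4% of the change was kept with the Gapdh and actin ratios as covariates. Loss of whole Purkinje cells as the only cause could not be told apart from lower expression in cells that remain. Over 5 markers of Purkinje cells alone, the range of changes exceeded the largest difference between probe sets of 1 gene in A39 at 4 months (0.49 against 0.43) and A61 (0.48 against 0.36), and did not in A39 at 10 months (0.22 against 0.32), S46 at 10 months (0.79 against 0.92) or S25 (0.88 against 0.89). The squared spread of these 5 changes over that expected from their errors ran the other way, except in A39 at 10 months. It was 1.07 and 1.03 in A39 at 4 months and A61, and 2.53 and 3.19 in S46 at 10 months and S25. In A39 at 10 months it was 0.177, so both measures were low there. As these measures disagree in all comparisons but that one, the question stayed open.

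The second pattern was that the 3 transgenic arrays of S46 at 10 months, labelled female, had male Xist and Eif2s3y signals, with sex labels met in 45 of 48 arrays. A sex difference like that in groups with both sexes was excluded as the main cause of the 74 calls there. Over these 7 groups (26 arrays) the median male minus female effect in the direction of the call was 0.0032, against a median call of 0.93. It had the direction of the call in 37 of 74. A sex effect particular to this line at 10 months could not be excluded. As 0 arrays labelled male had a female pattern, an exchange of female S46 animals with male arrays of this series was excluded. If the sex label is wrong, an exchange between males would leave no such trace, so it could not be told. A wrong sex label and samples from outside the series remain possible.

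The third pattern was that S46 at 3.5 months had 0 calls where S25 at 3 months had 272. Noisy arrays were excluded only as what hid the falls of S25. Without the arrays of lowest agreement, the probe sets that fell in S25 had a median of 0.016 in S46 at 3.5 months, against -0.97 in S25. This cannot tell whether noise hid other changes. The median SD within groups was 0.276 in S46 at 3.5 months, against 0.230 in S25. Whether the S46 animals carried the transgene could not be told from the mouse Htt signal (-0.080), since that probe set is not known to read it.

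Exchanging genotypes within comparisons asked whether chance could give the counts. Of 35 splits, 1, the real one, gave as many calls in A39 at 4 months (118, highest other 2) and A61 (19, highest other 3). This is the smallest share that 35 splits allow, and it was not adjusted over the comparisons. The counts there argue against chance but do not exclude it. With 3 against 3 arrays only 10 splits exist, too few to decide; the real one alone (1 of 10) gave as many in A39 at 10 months (141, highest other 2), S46 at 10 months (74, highest other 0), S25 (272, highest other 10) and X50 (2, highest other 1). In S46 at 3.5 months all 35 splits gave at least the 0 of the real one, and the highest gave 131, with transgenic array 3 and control arrays 1, 3 and 4 on one side. That split is the real one with only transgenic array 3 and control array 2 exchanged. It joins the 2 arrays of lowest agreement in the series, control array 4 (0.897) and transgenic array 3 (0.903). Whether genotype or another structure of the samples gave its count cannot be told.

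Differences between effects that passed were 30 for S46 at 10 against 3.5 months, 2 for NLS against NES, 2 for S46 against A39 at 10 months, 151 for S25 against S46 and 38 for S46 against X50. Exchanging genotypes within each comparison decided nothing for a difference, since a split that keeps or fully exchanges the genotypes of 1 comparison leaves its real effect standing. Of 100 splits, at least as many calls came in 16 for S46 at 10 against 3.5 months (30, highest other 81, with the arrays of 10 months kept), 18 for NLS against NES (2, highest other 130), 9 for S46 against A39 (2, highest other 74, with the arrays of A39 kept), 5 for S25 against S46 (151, highest other 255, with those of S25 fully exchanged) and 2 for S46 against X50 (38, highest other 43). All 100 gave at least the 0 of A39 at 10 against 4 months (highest other 126) and of A61 against A39 (highest other 65). Splits with many more calls than the real one thus point to a structure of the samples, the genotype effects themselves among it.

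Arrays far from the other 3 of their group were found in 14 of 212 tests, where 10.6 were expected, as chance flags about 1 in 20 groups. The gap over the range was 0.842 for the actin ratio of transgenic array 4 in A39 at 4 months (1.80, the others 1.23 to 1.32) and 0.97 for the agreement of control array 4 in S46 at 3.5 months (0.897, the others 0.934 to 0.935). Marker scores stood apart for Purkinje markers in transgenic array 3 of A61 (0.847; a score of -0.11, the others -0.45 to -0.40), granule markers in transgenic array 3 of S46 at 3.5 months (0.883; -0.24, the others 0.08 to 0.13), and choroid plexus markers in transgenic array 1 of A39 at 4 months (0.89; -0.80, the others 0.89 to 1.10) and control array 4 of A61 (0.867; -0.77, the others 0.20 to 0.35). Among genes, at 4 months in A39, Htt stood apart in control array 2 (0.987), Acads in transgenic array 4 (0.841), Alcam in transgenic array 1 (0.84), Pcp2 in transgenic array 3 (0.858), Cldn11 in transgenic array 4 (0.834) and Atp2a3 in control array 4 (0.852). In A61 they were Zdhhc14 in transgenic array 3 (0.855) and Ywhah in control array 4 (0.85).

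In 2 record files, those of A39 control array 2 at 4 months and S46 control array 1 at 10 months, the scan day was that of the other's group, while the signals correlated more with their own group (0.948 against 0.94, and 0.967 against 0.93).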

How the results depend on the processing

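Every called named gene kept its sign in every alternative, and so did the median of every called list except oligodendrocyte genes in A39 at 10 months (-0.06, and 0.04 without transgenic array 1, where the list did not pass). Over all settings, 4959 values of named genes kept their side of the threshold, 799 lost the call and 6 gained it; for lists 552 kept it and 130 lost it. Of the named calls of differences, 1 of 7 (S46 at 10 against 3.5 months), 0 of 2 (S46 against A39 at 10 months), 5 of 12 (S25 against S46) and 5 of 9 (S46 against X50) passed in every setting. The deposited values were already scaled, so leaving out scaling tested nothing. Quantile normalization gave 110, 164, 22, 0, 76, 285 and 3 probe sets in A39 at 4 and 10 months, A61, S46 at 3.5 and 10 months, S25 and X50, of which 96, 138, 17, 0, 70, 251 and 2 were among those of the scaled values (118, 141, 19, 0, 74, 272 and 2). Without detection calls there are limits to what can be said of weak signals.

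Where a count moved by over 1.5 times, the cause was not tested, apart from fits to fewer arrays. Fitted to only the arrays compared, which leaves fewer residual degrees of freedom, the counts were 23 in A39 at 4 months, 42 in A39 at 10 months, 5 in A61, 73 in S25, 0 in X50, and, for differences, 6 (S46 at 10 against 3.5 months), 0 (NLS against NES), 1 (S46 against A39 at 10 months) and 50 (S25 against S46). Array weights gave 202, 607, 120, 1, 370 and 11 in A39 at 4 and 10 months, A61, S46 at 3.5 and 10 months and X50, and, for differences, 87 (S46 at 10 against 3.5 months), 3 (A39 at 10 against 4 months), 0 (NLS against NES), 31 (S46 against A39 at 10 months), 2 (A61 against A39) and 157 (S46 against X50). Without a filter A61 had 12, S46 at 3.5 months 6, X50 1, NLS against NES 5 and A61 against A39 1; with the 60th percentile filter S46 at 3.5 months had 1, NLS against NES 5 and S46 against A39 at 10 months 1. With sex labels as a covariate X50 had 1 and S46 against A39 at 10 months 5, and with scan day 1 and 1.

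Arrays share replicate numbers but no pairing is described, and in only 6 of 24 pairs did r exceed 0.1 after removal of group means. With a replicate block the counts were 91, 123, 11, 1, 70, 243 and 0 in the order above, 0 for NLS against NES and 25 for S46 against X50. Of the alternatives chosen after seeing the data, sex from signals gave 1 in X50 and 0 for S46 against A39 at 10 months. The fluidics station gave 122 in S25, 4 in X50, 1 for NLS against NES, 1 for S46 against A39 at 10 months, 90 for S25 against S46 and 23 for S46 against X50. Without the 4 arrays of lowest agreement S46 at 10 against 3.5 months had 48 and NLS against NES 0, and with 2 arrays exchanged S46 at 10 months had 63 (56 of them among the 74), NLS against NES 1 and S46 against A39 at 10 months 1. Male arrays of S25 gave 131, and A61 without the 3 controls titled A39 gave 6. Animal identifier prefix as a random block had a consensus correlation of 0.0373.

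With 1 array left out, the counts ran from 67 to 112 in A39 at 4 months (67 without transgenic array 3), from 80 to 121 in A39 at 10 months (91 and 80 without control arrays 1 and 2, 88 and 82 without transgenic arrays 1 and 2), from 7 to 31 in A61 (8 and 10 without control arrays 1 and 3; 11, 7, 31 and 9 without transgenic arrays 1 to 4), from 0 to 5 in S46 at 3.5 months (5 without control array 1, 2 without transgenic array 1, 1 without control array 2 or 3 or transgenic array 2 or 3), from 43 to 70 in S46 at 10 months (44 and 43 without transgenic arrays 1 and 2, 49 without control array 3), from 186 to 248 in S25, and from 0 to 3 in X50 (0 without control array 3, transgenic array 1 or transgenic array 3, and 1 without transgenic array 2).

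For differences these ranges were 21 to 36 for S46 at 10 against 3.5 months, 0 to 1 for A39 at 10 against 4 months (1 without transgenic array 3 of 10 months), 0 to 7 for NLS against NES (7 and 0 without transgenic arrays 3 and 2 of S25, 6 and 0 without its controls 2 and 3, 4 and 5 without transgenic array 3 and control array 2 of S46, 0 and 1 without transgenic arrays 1 and 2 of A39, 0 without transgenic array 3 of A61), 0 to 2 for S46 against A39 at 10 months (0 without control array 1 or 2 or transgenic array 3 of A39 or transgenic array 2 of S46, 1 without transgenic array 1 or 2 of A39 or without transgenic array 1 or 3 or control array 1 or 2 of S46), 108 to 178 for S25 against S46, 0 to 4 for A61 against A39 (4 without transgenic array 2 of A61, 1 without its transgenic array 3 or control array 4) and 24 to 41 for S46 against X50 (24 without transgenic array 2 of S46).

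The counts of lists past the threshold, 11, 12, 8, 3, 8, 11 and 5 in the order above, were 5, 3, 1, 0, 3, 5 and 0 with an estimated correlation. Fry gave 0 in S46 at 3.5 months, 4 in S46 at 10 months and 0 in X50, and in S46 at 3.5 months quantile normalization and the mean of a gene's probe sets each gave 0. Leave-one-out ranges for lists and correlations were added after seeing the data: 9 to 12, 8 to 12, 7 to 9, 0 to 4 (0 without transgenic array 4 or control array 4), 7 to 9, 8 to 12, and 3 to 6 (3 without control array 3 of X50). In the 335 fits in which a called list kept its call with 1 array left out, its median moved by more than 1.5 times in 28, to a larger value in 20 and a smaller one in 8. The median r over the 15 pairs of comparisons of 142 glutamine lines, 0.319, was 0.746 across genes called in either, and 0.216 to 0.364 with 1 array left out.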

Other observations

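Sex gave a known difference against which the genotype effects can be read. Over the groups with both sexes Xist, the RNA that silences an X chromosome, was lower in males by -5.27, Eif2s3y, a translation factor gene of the Y, higher by 2.84, and Eif2s3x, its X copy, lower by -0.43. In S46 at 10 months the transgenic arrays differed from the controls by -5.12 (SE 1.65, adjusted p = 0.19) in Xist and by 3.30 (SE 0.94, adjusted p = 0.0939) in Eif2s3y; neither passed the limma threshold.

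The lists that passed in no comparison were vascular and endothelial markers (lowest adjusted p = 0.365, in A61), brainstem and midbrain markers (lowest 0.123, in A61, median -0.25) and p53 targets (lowest 0.187, in S46 at 3.5 months, median 0.14). Choroid plexus scores per array differed by 0.57 in A39 at 4 months (exact p = 0.343), 0.62 at 10 months (exact p = 0.1), -0.23 in A61 (exact p = 0.714), -0.49 and 0.93 in S46 at 3.5 and 10 months (exact p = 0.457 and 0.1), 0.79 in S25 (exact p = 0.2) and 0.32 in X50 (exact p = 0.4), and the lowest adjusted p was 0.28. Median, mean and test differed in sign for some lists that did not pass. Heat shock genes in A39 at 4 months had a median of 0.02 and a mean of -0.02, Bergmann glia markers in A39 at 10 months -0.03 and 0.03, and meninges markers there -0.01 and 0.07. In A61 p53 targets had 0.05 and -0.02, in S46 at 10 months receptor genes 0.02 and -0.04, in S25 oligodendrocyte genes -0.02 and 0.03, and in X50 brainstem markers 0.02 and -0.15.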
